A study of Homo sapiens with 12 samples.

How the data were processed

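RNA of THP1 cells was sequenced in 12 libraries, made from total RNA with a stranded mRNA kit per the labels' protocols. The labels place 3 libraries in each of 4 groups: TFEB wild type (WT) or TFEB-S401A knock-in cells, each with DMSO or with 50 ng/ml PMA for 6 h. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, or how many edited clones were used, so p-values measure only the spread between these samples, which may be technical.

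The deposited gene counts are whole numbers of fragments per gene, not normalised. Per the file headers the authors counted them with featureCounts 1.5.2 over hg38 RefSeq exons, reverse-stranded, with both ends mapped, no chimeric fragments and a minimum overlap of 25 bases. Per the submitters' processing notes the reads were aligned with STAR 2.5.2b to GRCh38, and DESeq2 is named without a role. The authors' second table holds FPKM values. Recomputing each FPKM from the deposited counts, the exon length and the column total gave the deposited value within a relative tolerance of 1e-06, so this table carries no correction for library composition. It covers the same 28395 genes, of which 27745 matched a gene symbol and 7241 had no count in any library. Genes without a symbol held 0.05% of the counts.

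Totals per library ran from 24696568 to 44015369 counts. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, its default filter on low counts, a model of 4 group means over all 12 libraries and the robust quasi-likelihood F test. Benjamini-Hochberg adjustment ran over the 15073 genes that passed the filter, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene comes from this test unless another is named. The common biological coefficient of variation was 0.207. Standard errors of log2 fold changes are the absolute log2 fold change over the square root of F. Levels are CPM, counts scaled to TMM-adjusted library sizes, as mean ± SD of 3 libraries. The 5 contrasts were PMA over DMSO in each genotype, S401A over WT in each treatment, and the interaction, which is the PMA effect in S401A less that in WT.

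Before the data were examined, 31 gene lists were fixed. They were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists within a contrast. An estimated correlation and the rotation test fry stand beside it. The design, the gene lists, the alternatives and a rule for the genes to name were also fixed then. The rule takes, per contrast, the 6 largest called changes of protein-coding genes in each direction with a group mean of at least 5 CPM and no overlap between groups, at most 4 members of each list with the smallest adjusted p, and a set of genes always named. It took 142 to 148 genes per contrast. The text draws its genes from a smaller set of 41 to 60 per contrast, chosen after their values had been seen, and does not name all of that set. Results for some genes are not reported here.

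The alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, no filter or a filter of 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, fits on the 2 groups compared, and leaving out each library. Chosen after seeing the data were offsets corrected for a trend on exon length (lowess span 0.3), limma's voom with library quality weights, gene lists without WT PMA replicate 1, counts and lists without genes of chromosomes 10 and 12, and simulated libraries without a difference between the lines. Counts of list members on log2(FPKM + 1) were also chosen then. Chromosome positions were compared in segments of 50 neighbouring tested genes, against 1000 shuffles of gene positions. Figures were drawn with matplotlib 3.10.9.

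The tests were also run on simulated counts of the same 15073 genes with 200 genes changed. Those simulations were written after the first runs on the deposited counts. Of genes changed 4-fold, edgeR recovered 90.9% for PMA in WT, 92.4% for PMA in S401A, 87.9% for genotype in DMSO, 84.8% for genotype in PMA and 68.2% for the interaction. Of genes changed 2-fold it recovered 44.8%, 46.3%, 52.2%, 55.2% and 9% in the same order, and of genes changed 1.5-fold 4.5%, 4.5%, 1.5%, 11.9% and 0%. False calls made up 7%, 5.9%, 6%, 2.9% and 1.9% of calls. An uncalled gene is therefore not shown to be unchanged, least of all in the interaction. Each gene was simulated with the same spread in all groups. In the deposited counts WT PMA had a median SD of 0.438 log2 units, against at most 0.11 in the other groups. Libraries simulated with each group's own spread and no line difference gave 272 to 378 calls for genotype in PMA. The shares recovered and false may thus differ in the deposited counts. Counts of genes with near-identical copies can be split between copies by the counting and are uncertain.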

Results

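RNA was sequenced from THP1, an established human leukaemia line of monocytic type, in which TFEB was either wild type (WT) or carried the CRISPR knock-in S401A, an exchange of a serine for alanine. TFEB is a transcription factor of the MiT/TFE family that acts on genes of lysosomes and autophagy. Cells of each genotype received DMSO, the solvent, or 50 ng/ml PMA for 6 h. PMA is a phorbol ester that activates protein kinase C and drives THP1 cells towards a macrophage state. The sample titles call the DMSO cells untreated, while their treatment label is DMSO. Each of the 4 groups held 3 libraries, with 24696568 to 44015369 counted fragments per library. By its title, the series concerns how p38 MAPK acts on TFEB when monocytes become macrophages.

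The first principal component of log2 CPM held 65.2% of the variance and parted DMSO from PMA, and the second held 17.4% and parted the genotypes. WT PMA replicate 1 stood apart from replicates 2 and 3 of its group, with a median absolute deviation of 0.714 log2 units from their mean, against at most 0.141 for a library of the other 3 groups. Its counts fell on shorter genes, with a mean exon length of 2951 bases against 3773 to 4212 in the other 11 libraries. Genes encoded in mitochondria took 3.57%, 4.36% and 5.17% of counts in S401A DMSO and 3.76%, 4.17% and 3.46% in S401A PMA. In WT they took 2.77%, 2.47% and 2.96% with DMSO and 1.77%, 2.79% and 2.71% with PMA.

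**Figure D1:**
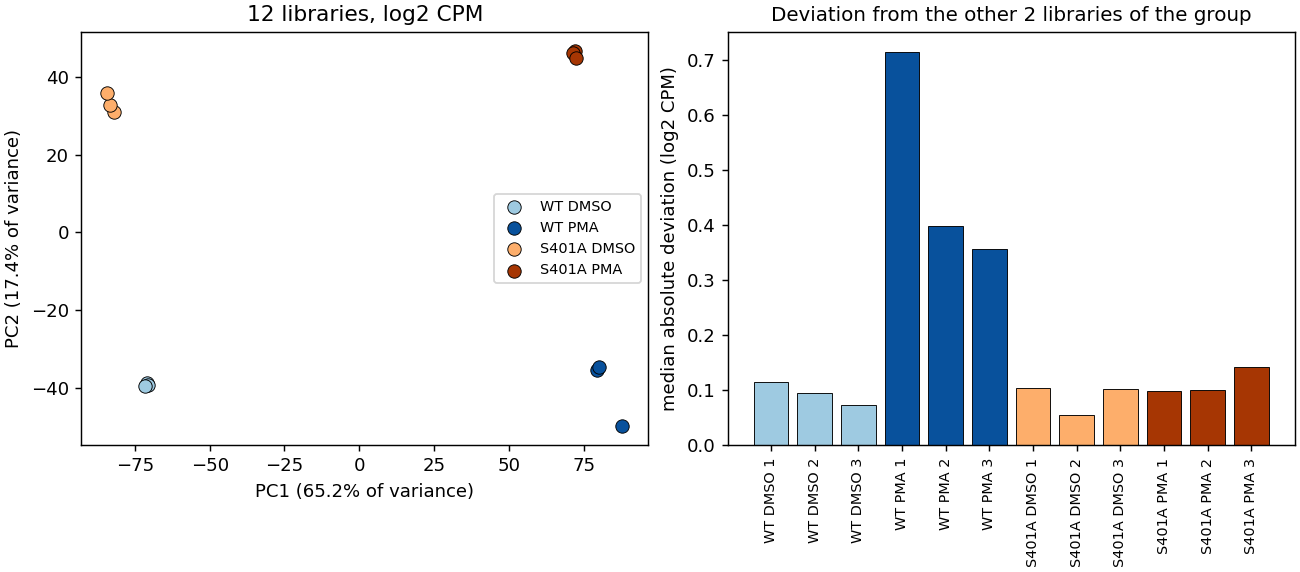
Left, first and second principal components of log2 CPM for the 12 libraries, coloured by group, with the percent of variance on each axis. Right, bars give each library's median absolute deviation in log2 CPM from the mean of the other 2 libraries of its group, and WT PMA replicate 1 reaches 0.714 while the other 3 groups stay at or under 0.141.

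TFEB (Entrez gene 7942, hg38 chromosome 6, 41683978 to 41736259, minus strand) was measured in every library. Its levels were 25.6, 21.5 and 20 CPM in WT DMSO, 86.7, 36.8 and 40.8 in WT PMA, 28.5, 31.1 and 29.2 in S401A DMSO, and 43.1, 42.8 and 45.5 in S401A PMA. The transcript level does not check a label for a codon change. TFEB rose with PMA in WT by 1.29 ± 0.27 on the log2 scale (SE, n = 3, adjusted p = 0.00254), and by 0.79 without WT PMA replicate 1. In S401A its PMA change was 0.56 ± 0.27 (adjusted p = 0.109), and S401A over WT was 0.40 ± 0.27 in DMSO (adjusted p = 0.346) and -0.32 ± 0.27 in PMA (adjusted p = 0.405), none of them called. The first 2 of these were called without WT PMA replicate 1, at 0.57 and 0.40, as they were on the 2 groups alone (0.56 and 0.42) and with voom (0.50 and 0.52), and the PMA change also with length-corrected offsets (0.66). The difference in PMA was 0.18, of the opposite sign, without WT PMA replicate 1, -0.54 without replicate 2 and -0.50 without replicate 3, and not called. The interaction of -0.73 ± 0.38 was not called either (adjusted p = 0.485). It was -0.22 without WT PMA replicate 1, and was called with voom, at -0.39.

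PMA over DMSO in WT cells asks what 6 h of PMA did with unedited TFEB. IL1B (Entrez gene 3553, hg38 chromosome 2, 112829751 to 112836779, minus strand), which encodes interleukin-1 beta, rose from 0.586 ± 0.11 to 866 ± 16.8 CPM (SD, n = 3), a log2 fold change of 10.50 ± 0.15 (SE, adjusted p = 3.88e-11). CXCL8, the neutrophil chemokine interleukin-8, rose from 2.59 ± 0.221 to 205 ± 35.3 CPM, and TNF (chromosome 6, 31575567 to 31578336) from 5.19 ± 0.231 to 128 ± 14.9 CPM. RGS1, a regulator of G protein signalling, rose from 0.424 ± 0.0632 to 944 ± 16.4 CPM and EMP1 from 0.162 ± 0.0702 to 349.8 ± 112.3 CPM. KIT, the stem cell factor receptor, changed by -6.43 ± 0.32 on the log2 scale (-7.22 without WT PMA replicate 2), SERPINB2 by -5.77 ± 0.23 and SELPLG, the P-selectin ligand, by -4.96 ± 0.23. Among cytokines and chemokines, 26 of 30 tested members rose (26 higher adjusted over the list alone, camera adjusted p = 1.29e-13).

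Of immediate early and AP-1 genes, 24 of 27 tested members rose and 1 fell (24 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.98e-13), among them EGR1 from 3.75 ± 0.303 to 1062 ± 159.6 CPM, ATF3 from 1.77 ± 0.277 to 55.4 ± 1.92 CPM and FOS from 21.6 ± 0.694 to 195 ± 24 CPM. Of MAPK phosphatases and feedback genes, 14 of 17 tested members rose and 1 fell (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.61e-07, 11 higher and 3 lower on log2(FPKM + 1)). There DUSP6 was at 5.11 ± 0.21 and PHLDA1 at 8.44 ± 0.17. Of NF-kappaB targets, 21 of 27 tested members rose and 1 fell (22 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.2e-09). There CD83 was at 6.03 ± 0.11, ICAM1 at 5.35 ± 0.16 and NFKBIA, the inhibitor of NF-kappaB, at 2.39 ± 0.11. Of macrophage markers, 21 of 31 tested members rose and 3 fell (21 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.04e-06, 18 higher and 6 lower on log2(FPKM + 1)). The scavenger receptor CD36 rose from 33.6 ± 2.56 to 605 ± 114.9 CPM and CSF1R, the receptor of macrophage colony-stimulating factor, from 125 ± 7.55 to 366 ± 52.6 CPM. CD14 changed by -1.85 ± 0.33 and was low, at 3.61 ± 0.376 CPM in DMSO. ITGAM was not called, at -0.26 ± 0.21 (adjusted p = 0.325). It was at 0.00 without WT PMA replicate 1 and -0.42 without replicate 3, and was called on log2(FPKM + 1), at -0.66.

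Genes of DNA replication fell, with MCM3 from 528 ± 16 to 170.3 ± 6.34 CPM and MCM6 from 267 ± 1.48 to 103 ± 2.63 CPM. In that list 23 of 39 tested members fell and 1 rose (1 higher and 23 lower adjusted over the list alone, camera adjusted p = 7.61e-07). With an estimated correlation the list had an adjusted p = 0.0317. Without genes of chromosomes 10 and 12 it stayed called with the preset correlation (camera adjusted p = 5.42e-06), but not with an estimated correlation (adjusted p = 0.127). MYB and MYC, which are active in proliferating progenitors, changed by -1.03 ± 0.12 and -1.10 ± 0.11. Of lysosomal hydrolases and membrane proteins, 23 of 41 tested members rose and 1 fell (23 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000243, adjusted p = 0.281 with an estimated correlation), against 15 higher and 10 lower on log2(FPKM + 1). There the protease CTSL went from 62.7 ± 2.21 to 1821 ± 525 CPM and SCARB2 was at 1.98 ± 0.15. Of subunits of the V-ATPase, the proton pump of lysosomes, 16 of 18 tested members rose and 1 fell (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.194 with an estimated correlation). There ATP6V0A1 was at 2.24 ± 0.09. Of autophagy genes, 15 of 38 tested members rose and 7 fell (17 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.134), against 8 higher and 14 lower on log2(FPKM + 1). SQSTM1, the receptor p62, rose from 78 ± 3.71 to 998 ± 241 CPM. GPNMB (chromosome 7, 23246686 to 23275110), a known MiT/TFE target, rose from 32.3 ± 0.337 to 170.0 ± 38.6 CPM. TFE3 and MITF, relatives of TFEB, rose by 1.07 ± 0.11 and 1.09 ± 0.17. MITF was not called on log2(FPKM + 1), at 0.30, or on log2(FPKM + 0.1), at 0.55.

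In all, 4025 genes were higher and 3900 lower with PMA in WT, of which 2188 and 2151 differed at least 2-fold. On log2(FPKM + 1), which is not corrected for library composition, the median of all genes was -0.24 against 0.05, and the counts were 1955 higher and 6561 lower. Medians of the lysosomal and autophagy lists lay 0.2 and 0.08 above that median of all genes.

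PMA over DMSO in S401A cells asks the same of the knock-in line. GDF15, a stress cytokine, rose from 0.124 ± 0.0122 to 434 ± 34.8 CPM (SD, n = 3, adjusted p = 1.38e-08). RGS1 rose from 0.0936 ± 0.0425 to 234 ± 2.95 CPM and ATF3 from 1.22 ± 0.151 to 235 ± 3.84 CPM. IL1B rose from 1.47 ± 0.049 to 182 ± 2.38 CPM, CXCL8 from 1.87 ± 0.103 to 106 ± 3.21 CPM and TNF from 0.525 ± 0.14 to 14 ± 0.322 CPM. SERPINB2 changed by -6.34 ± 0.24, KIT by -4.65 ± 0.28 and NFE2, a transcription factor of the megakaryocyte and erythroid lines, by -4.95 ± 0.38.

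Of cytokines and chemokines, 26 of 30 tested members rose (26 higher adjusted over the list alone, camera adjusted p = 2.2e-13), and of immediate early and AP-1 genes 24 of 27 tested members rose and 2 fell (24 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.2e-13). Of MAPK phosphatases and feedback genes, 14 of 17 tested members rose (15 higher adjusted over the list alone, camera adjusted p = 1.7e-08). Of NF-kappaB targets, 22 of 27 tested members rose and 1 fell (22 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.76e-08). There ICAM1 was at 3.09 ± 0.14. Of macrophage markers, 20 of 31 tested members rose and 2 fell (20 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.64e-07). There CD36 went from 40 ± 1.69 to 976 ± 45.9 CPM and CSF1R from 124 ± 3.84 to 355 ± 22.6 CPM. Among DNA replication genes 31 of 39 tested members fell (33 lower adjusted over the list alone, camera adjusted p = 5.18e-09). There MCM3 was at -1.67 ± 0.09. Of interferon-stimulated genes, the antiviral genes that interferons induce, 27 of 38 tested members rose and 2 fell (27 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.13e-07). EPSTI1 rose from 3.36 ± 0.159 to 41.5 ± 2.63 CPM, IFI44 from 3.52 ± 0.211 to 22.8 ± 0.813 CPM and IFIT1 from 2.38 ± 0.183 to 17.1 ± 0.942 CPM. In WT the same list had 18 members that rose and 13 that fell (18 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.577), against 10 higher and 16 lower on log2(FPKM + 1). EPSTI1 was higher with PMA in WT as well, at 1.33 to 1.69 CPM in DMSO and 7.42 to 8.76 in PMA. So were IFI44 (0.935 to 1.295 and 2.77 to 3.09 CPM) and IFIT1 (0.252 to 0.3575 and 1.21 to 2.07 CPM).

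Of lysosomal hydrolases and membrane proteins, 23 of 41 tested members rose and 4 fell (23 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000578, adjusted p = 0.295 with an estimated correlation, 19 higher and 7 lower on log2(FPKM + 1)). There CTSL went from 65.4 ± 2.44 to 1292 ± 60.5 CPM and the acid ceramidase ASAH1 from 118.8 ± 4.83 to 367 ± 6.96 CPM. Of V-ATPase subunits, 15 of 18 tested members rose (16 higher adjusted over the list alone, camera adjusted p = 2.73e-06, adjusted p = 0.116 with an estimated correlation). There ATP6V0A1 was at 2.68 ± 0.10. Of autophagy genes, 15 of 38 tested members rose and 7 fell (15 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.116 with an estimated correlation, adjusted p = 0.141 without genes of chromosomes 10 and 12), against 9 higher and 10 lower on log2(FPKM + 1). There SQSTM1 went from 95.9 ± 1.28 to 1654 ± 71 CPM. Of mTORC1 and Rag GTPase genes, 13 of 27 tested members rose and 6 fell (13 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.14, 9 higher and 8 lower on log2(FPKM + 1)), with FNIP2, a partner of folliculin, at 3.84 ± 0.27, RRAGC at 1.27 ± 0.09, FLCN at 1.52 ± 0.15 and DEPTOR, an inhibitor of mTOR, at -4.09 ± 0.15. GPNMB rose from 31.9 ± 1.76 to 489 ± 4.43 CPM and MITF by 1.89 ± 0.17.

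PMA in S401A gave 3637 genes higher and 3862 lower, 1949 and 2146 of them at least 2-fold. The WT PMA libraries enter this fit only through the shared spread, and without WT PMA replicate 1 the counts were 5836 and 5880. On log2(FPKM + 1) they were 2362 and 5611, and the median of all genes was -0.16 against -0.01.

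**Figure D2:**
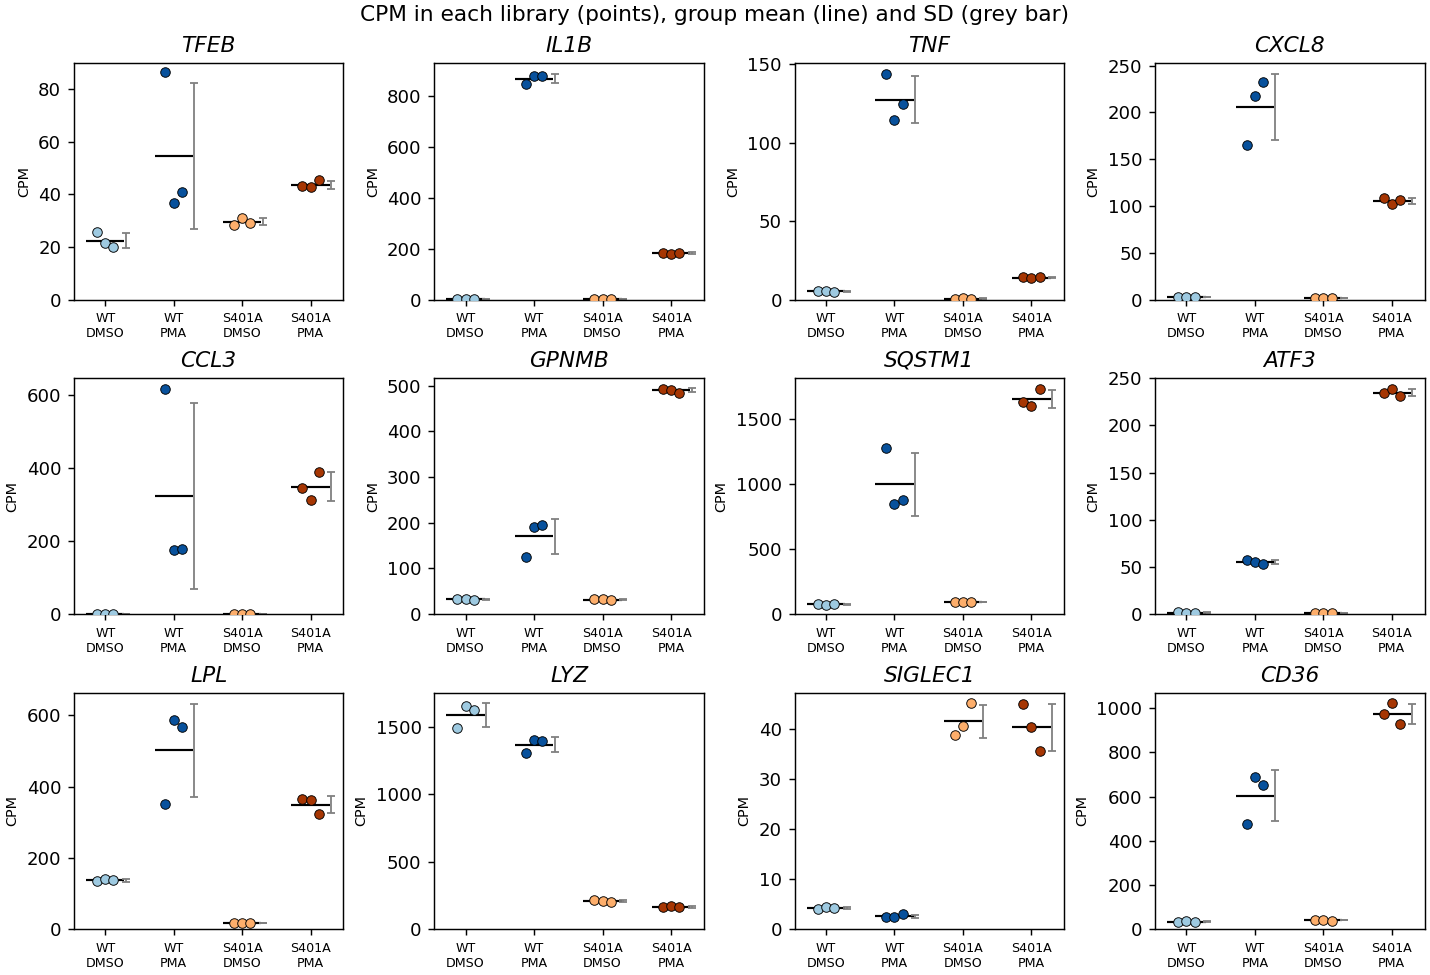
CPM of 12 genes on linear axes from 0, with a point per library, a line at each group mean and a grey bar of 1 SD, for WT DMSO, WT PMA, S401A DMSO and S401A PMA (n = 3 each). IL1B reaches 866 ± 16.8 CPM in WT PMA and 182 ± 2.38 in S401A PMA, and GPNMB 170.0 ± 38.6 and 489 ± 4.43.

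S401A over WT in DMSO asks how the lines differed without PMA. LYZ, which encodes lysozyme, was lower in S401A, at 206 ± 8.41 against 1592 ± 89 CPM (SD, n = 3; log2 fold change -2.95 ± 0.10 SE, adjusted p = 8.42e-08). The lipoprotein lipase gene LPL was lower at 17.2 ± 0.752 against 137 ± 3.91 CPM, the proteoglycan gene VCAN at 6.86 ± 0.832 against 134 ± 8.73 CPM and TNF at 0.525 ± 0.14 against 5.19 ± 0.231 CPM. SIGLEC1, a macrophage lectin induced by interferon, was higher at 41.5 ± 3.27 against 4.22 ± 0.15 CPM, and so were PRDM6 at 26.4 ± 1.5 against 1.17 ± 0.106 CPM, PCDH7 at 66.2 ± 2.53 against 2.52 ± 0.125 CPM and ITGAM, the integrin CD11b, at 125 ± 4.91 against 40.3 ± 0.406 CPM. CD14 differed by -3.04 ± 0.35 and FLT3, a receptor of progenitors, by -1.82 ± 0.16.

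Of interferon-stimulated genes, 18 of 38 tested members were higher in S401A and 3 were lower (20 higher and 3 lower adjusted over the list alone, camera adjusted p = 2.08e-06, adjusted p = 0.057 with an estimated correlation). IFIT1 differed by 2.98 ± 0.22, IFI44 by 1.64 ± 0.13, RSAD2 by 1.34 ± 0.11 and GBP2 by -1.81 ± 0.15. Of ribosome biogenesis genes and MYC targets, 14 of 36 tested members were lower (16 lower adjusted over the list alone, camera adjusted p = 6e-05, adjusted p = 0.26 with an estimated correlation). There WDR12 was at -0.61 ± 0.08. Of mitosis genes, 9 of 36 were lower and 2 higher (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.26 with an estimated correlation), with the kinase gene AURKA at -0.61 ± 0.08. MAPK phosphatases and feedback genes had 7 of 17 lower and 3 higher (3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.26 with an estimated correlation). There SPRY4 was at -2.18 ± 0.28, and without WT PMA replicate 1 the list was not called (adjusted p = 0.0808). The ATF4 and unfolded protein response list had 12 of 30 lower and 3 higher (3 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.474 with an estimated correlation), with the amino acid transporter SLC7A5 at -1.42 ± 0.12. Mitochondrially encoded genes had 8 of 15 higher (9 higher adjusted over the list alone, camera adjusted p = 0.000964, adjusted p = 0.26 with an estimated correlation), and MT-ND1, at 0.77 ± 0.15, was no longer called with length-corrected offsets, at 0.62. Lysosomal genes went both ways, with 4 of 41 higher, such as CTSK at 2.83 ± 0.15, and 7 lower (4 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.955, 7 higher and 7 lower on log2(FPKM + 1)). GPNMB differed by -0.02 ± 0.15 (adjusted p = 0.958) and SQSTM1 by 0.30 ± 0.15 (adjusted p = 0.196), neither called. GPNMB was at -0.06 without S401A DMSO replicate 2 and 0.03 without replicate 3. SQSTM1 was called without WT PMA replicate 1 (0.30), on the 2 groups alone (0.32), on log2(FPKM + 1) (0.30), on log2(FPKM + 0.1) (0.32) and with voom (0.29).

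Genes of chromosome 10 as a group were higher in S401A, with a median 0.49 above that of other chromosomes, and genes of chromosome 12 lower, with a median difference of -0.34. Of 544 tested genes on chromosome 10, 222 were called higher and 12 lower, and of 767 on chromosome 12, 35 and 248. IFIT1 lies on chromosome 10, and LYZ on chromosome 12. Over all chromosomes 1738 genes were higher and 1721 lower in S401A, 736 and 715 of them at least 2-fold, and without genes of chromosomes 10 and 12 the counts were 1444 and 1429. Without WT PMA replicate 1, which enters only through the shared spread, they were 4385 and 4636, without WT DMSO replicate 2 1120 and 1160, and on log2(FPKM + 1) 2135 and 1388.

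**Figure D3:**
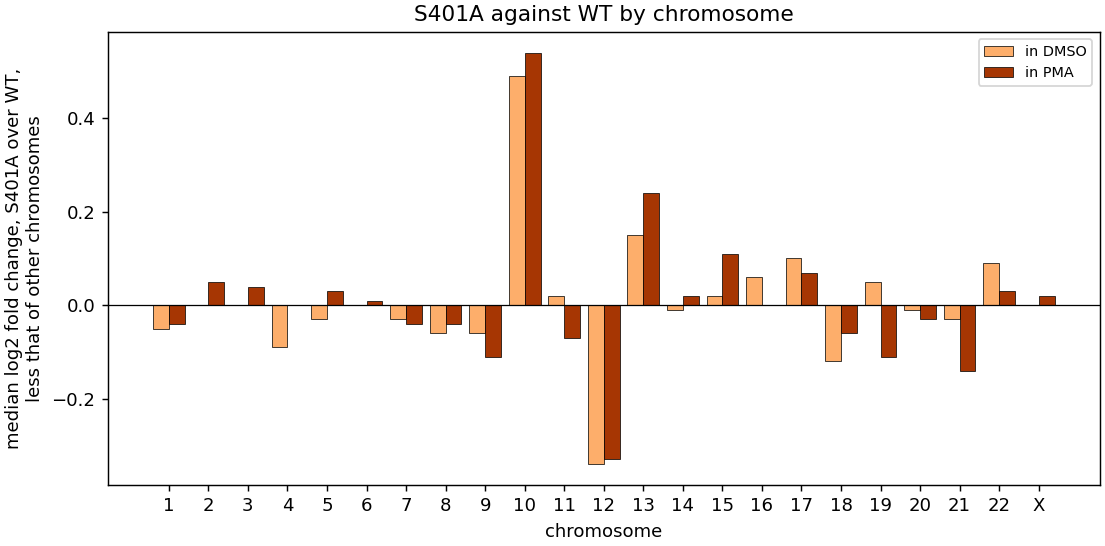
Bars give, for each chromosome, the median log2 fold change of its tested genes for S401A over WT less the median of all other chromosomes, in DMSO and in PMA (3 libraries per group). Chromosome 10 stands at 0.49 and 0.54 and chromosome 12 at -0.34 and -0.33, and the next, chromosome 13, at 0.15 and 0.24.

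S401A over WT in PMA asks how the lines differed after PMA. IL1B was lower in S401A, at 182 ± 2.38 against 866 ± 16.8 CPM (SD, n = 3; log2 fold change -2.25 ± 0.10 SE, adjusted p = 3.25e-07), as were TNF at 14 ± 0.322 against 128 ± 14.9 CPM and CXCL8 at 106 ± 3.21 against 205 ± 35.3 CPM. SPP1, which encodes osteopontin, was lower at 31.4 ± 3.41 against 283 ± 8.87 CPM, LYZ at 163 ± 4.38 against 1369 ± 54.3 CPM and the growth factor gene FGF2 at 0.906 ± 0.179 against 53 ± 20.8 CPM. GPNMB was higher at 489 ± 4.43 against 170.0 ± 38.6 CPM, ATF3 at 235 ± 3.84 against 55.4 ± 1.92 CPM, the metalloproteinase inhibitor TIMP3 at 1050 ± 17.2 against 176 ± 16 CPM and SIGLEC1 at 40.3 ± 4.76 against 2.54 ± 0.309 CPM. The integrin ITGAX, CD11c, was higher at 680.2 ± 42.8 against 288 ± 59.8 CPM, while CSF1R did not pass the test at -0.04 ± 0.11 (adjusted p = 0.808). CSF1R was called lower without WT PMA replicate 1 (-0.16) and with voom (-0.14), and was not called at -0.01 without WT PMA replicate 2, 0.03 without WT PMA replicate 3, -0.08 without S401A PMA replicate 1 and 0.01 without S401A PMA replicate 3.

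Of interferon-stimulated genes, 30 of 38 tested members were higher in S401A and 1 was lower (30 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.52e-18). There IFI44 was at 2.94 ± 0.13, XAF1 at 2.88 ± 0.13, RSAD2 at 2.34 ± 0.12 and RIGI, a sensor of viral RNA, at 2.11 ± 0.10. Autophagy genes had 10 of 38 higher and 1 lower (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.14 with an estimated correlation). There TECPR1 was at 1.04 ± 0.12, OPTN at 1.16 ± 0.17 and SQSTM1 at 0.73 ± 0.15. SQSTM1 was not called with length-corrected offsets (0.57) or on the 2 groups alone (0.72). Lysosomal genes had 8 of 41 higher, such as ASAH1 at 1.36 ± 0.10, and 9 lower (8 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.94), against 15 higher and 3 lower on log2(FPKM + 1). V-ATPase subunits had 5 of 18 higher and 2 lower (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.463, 8 higher and 0 lower on log2(FPKM + 1)), and without WT PMA replicate 1 the list was called higher (adjusted p = 0.0172). There ATP6V1A was at 1.29 ± 0.11. Of the 4 MiT/TFE factors, MITF at 1.31 ± 0.16, TFE3 at 0.39 ± 0.11 and TFEC at 0.90 ± 0.25 were higher and TFEB was not called (3 higher adjusted over the list alone, camera adjusted p = 0.13). TFE3 was not called without S401A PMA replicate 1 (0.35) or 3 (0.41), nor TFEC without replicate 1 (0.91) or 2 (0.86), and neither was on the 2 groups alone (0.38 and 0.89).

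NF-kappaB targets had 8 of 27 lower, such as TNFAIP8 at -2.25 ± 0.11 and TRAF1 at -1.35 ± 0.15, and 3 higher (4 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.407, 6 higher and 6 lower on log2(FPKM + 1)). Complement and phagocytic receptor genes had 11 of 28 lower, such as the complement gene C3 at -1.65 ± 0.10 and TLR2 at -1.34 ± 0.12, and 4 higher (4 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.14 with an estimated correlation), with a median of -0.28 and of 0.04 on log2(FPKM + 0.1). Without WT PMA replicate 1 that list was not called (adjusted p = 0.15). Mitosis genes had 14 of 36 lower and 1 higher (1 higher and 17 lower adjusted over the list alone, camera adjusted p = 0.000661, adjusted p = 0.14 with an estimated correlation). There AURKA was at -1.02 ± 0.08. Ribosome biogenesis genes had 16 of 36 lower (22 lower adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.187 with an estimated correlation). There DKC1 was at -0.52 ± 0.07, and not called on log2(FPKM + 1), at -0.32, or on log2(FPKM + 0.1), at -0.33. Mitochondrially encoded genes had 3 of 15 higher (2 higher adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.536 with an estimated correlation, adjusted p = 0.0576 without WT PMA replicate 1).

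Chromosome 10 again stood 0.54 above other chromosomes, with 245 genes called higher and 10 lower, and chromosome 12 at -0.33, with 60 and 268. OPTN lies on chromosome 10, and LYZ on chromosome 12. Of all genes 2181 were higher and 2074 lower in S401A, 923 and 825 of them at least 2-fold, and 1840 and 1762 without genes of chromosomes 10 and 12. Without WT PMA replicate 1 the counts were 4679 and 4448, on the 2 groups alone 880 and 764, and on log2(FPKM + 1) 2919 and 1098, with a median of all genes of 0.09 against -0.05.

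**Figure D4:**
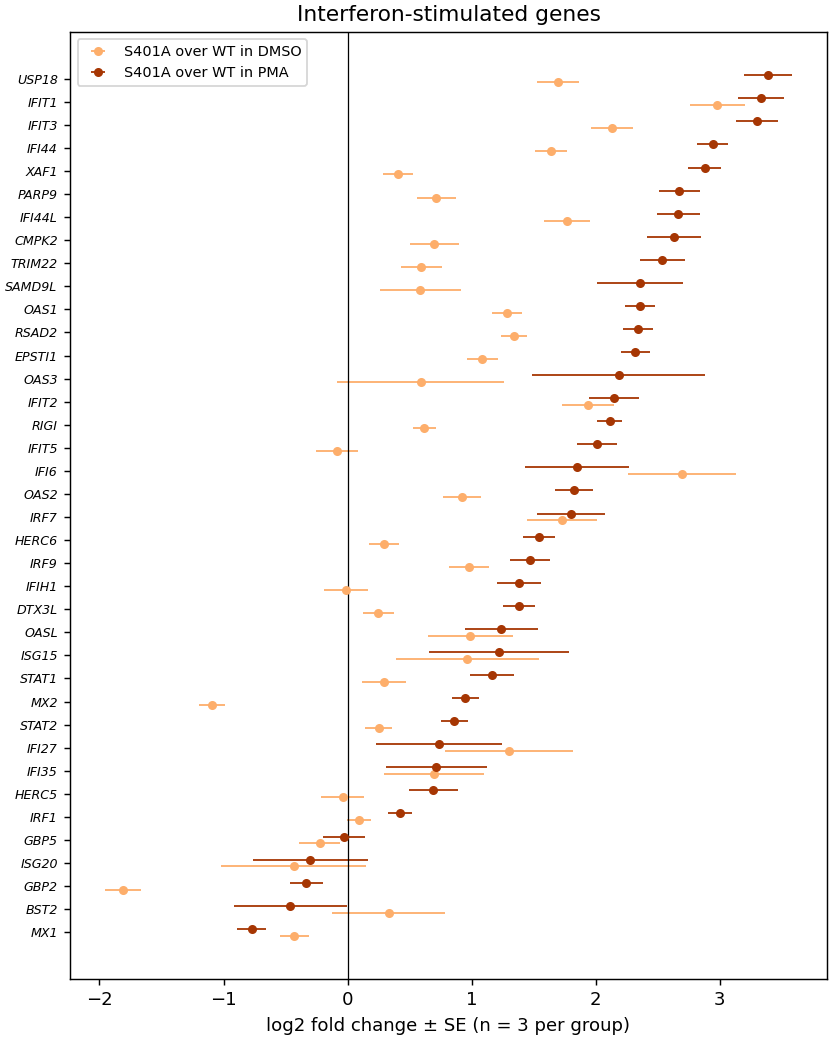
Log2 fold changes of S401A over WT in DMSO and in PMA for the 38 tested interferon-stimulated genes, ordered by the value in PMA, with bars of 1 SE (n = 3 per group). In PMA 30 genes are called higher and 1 lower, and in DMSO 18 and 3.

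The interaction asks whether the PMA response itself differed between the lines. IL1B rose less in S401A, with an interaction of -3.54 ± 0.16 on the log2 scale (SE, n = 3 per group, adjusted p = 3.41e-06), from a log2 rise of 10.50 ± 0.15 in WT and 6.95 ± 0.13 in S401A. ICAM1 at -2.27 ± 0.19 and CXCL1 at -2.29 ± 0.41 also rose less. CXCL1 was low, at 0.495 to 0.791 CPM in WT DMSO and 4.04 to 7.69 in WT PMA, against 0.407 to 0.556 and 0.765 to 0.875 in S401A. TNFAIP8 had an interaction of -1.59 ± 0.15, with a PMA change of 0.25 ± 0.10 in WT, not called (adjusted p = 0.0675) but called without WT PMA replicate 1 (0.27), and of -1.34 ± 0.11 in S401A. ATF3 rose more in S401A (2.63 ± 0.18), as did GPNMB (1.54 ± 0.21), LPL (2.47 ± 0.24) and FNIP2 (2.00 ± 0.35). LPL rose from a lower level in S401A and did not pass the WT level as a group. It was at 16.45 to 17.95 CPM in S401A DMSO and 321.9 to 364.5 in S401A PMA, against 133.3 to 141.1 and 350.3 to 588.2 in WT. DTX4, a ubiquitin ligase gene, had an interaction of 4.02 ± 0.18, MPEG1, which encodes a pore-forming protein of macrophages, 3.16 ± 0.18 and TIMP3 2.10 ± 0.14. MPEG1 was at 26.69 to 27.65 CPM in WT DMSO and 2.89 to 3.57 in WT PMA, against 18.39 to 21.45 and 18.64 to 24.01 in S401A. TNF at 0.10 ± 0.21 (adjusted p = 0.847), CXCL8 at -0.49 ± 0.19 (adjusted p = 0.276) and SQSTM1 at 0.43 ± 0.21 (adjusted p = 0.441) were not called, and TNF was of the opposite sign, at -1.12, and called on log2(FPKM + 1). TNF was low in S401A DMSO, at 0.384 to 0.664 CPM. SQSTM1 and CXCL8 were called without WT PMA replicate 1, at 0.65 and -0.62, as they were with voom (0.62 and -0.63), and SQSTM1 also on log2(FPKM + 1) (0.64) and log2(FPKM + 0.1) (0.63). With libraries left out, TNF was not called, and was at 0.19 without WT PMA replicate 1, 0.02 without WT PMA replicate 2, 0.06 without WT DMSO replicate 1, -0.09 without S401A DMSO replicate 1 and 0.32 without S401A DMSO replicate 2.

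Of interferon-stimulated genes, 17 of 38 tested members had a called positive interaction (23 higher adjusted over the list alone, camera adjusted p = 1.41e-20). XAF1 had an interaction of 2.47 ± 0.18, MX2 of 2.04 ± 0.15 and RIGI of 1.49 ± 0.13. Each of them was lower with PMA in all WT libraries and higher with PMA in all S401A libraries. Across the list in WT, 18 members rose and 13 fell with PMA, so these genes do not stand for all its members. XAF1 was at 27.7 to 29.8 CPM in WT DMSO and 5.51 to 7.93 in WT PMA, against 38.2 to 39 and 46.7 to 54.2 in S401A. MX2 was at 13.5 to 16.1 CPM in S401A DMSO against 30.1 to 33.7 in WT DMSO. Of lysosomal genes 2 had a called positive interaction, ASAH1 at 1.26 ± 0.14 and CTNS at 0.81 ± 0.15 (not called without S401A PMA replicate 1, at 0.77), and 1 of the 41 a called negative one (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.943, 4 higher and 1 lower on log2(FPKM + 1)). Of V-ATPase subunits ATP6V1A was called, at 1.00 ± 0.15 (2 higher adjusted over the list alone, camera adjusted p = 0.606), and without WT PMA replicate 1 the list was called higher (adjusted p = 0.0228). NF-kappaB targets had 4 of 27 with a called negative interaction (5 lower adjusted over the list alone, camera adjusted p = 0.06, adjusted p = 0.269 with an estimated correlation). Without genes of chromosomes 10 and 12 the adjusted p was 0.0443, and 0.231 with an estimated correlation. NRF2 and metallothionein genes had 2 of 20 with a called positive interaction, such as SRXN1 at 1.19 ± 0.12 (6 higher adjusted over the list alone, camera adjusted p = 0.00898, adjusted p = 0.416 with an estimated correlation).

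The interaction was called for 295 genes above 0 and 165 below 0, of which 196 and 95 reached 2-fold. Without WT PMA replicate 1 the counts were 1600 and 1198, and all 460 genes called with it remained called in the same direction. They were 188 and 88 without WT DMSO replicate 1, 186 and 85 without WT DMSO replicate 2, 181 and 80 without WT DMSO replicate 3, 198 and 100 without S401A DMSO replicate 1, 169 and 85 without S401A DMSO replicate 2, 181 and 92 without S401A DMSO replicate 3, 179 and 87 without S401A PMA replicate 1, 175 and 80 without S401A PMA replicate 2 and 194 and 90 without S401A PMA replicate 3.

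**Figure D5:**
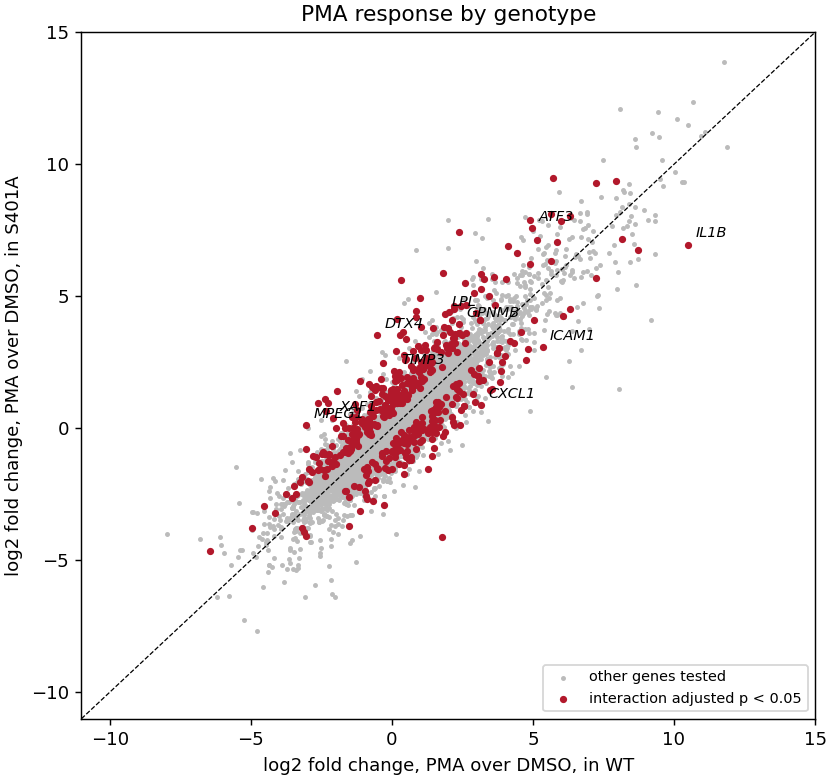
Each point is a tested gene, with the log2 fold change of PMA over DMSO in WT on the x axis and in S401A on the y axis, red where the interaction has an adjusted p under 0.05 (295 above and 165 below 0) and grey otherwise, and the dashed line marks equal responses. IL1B lies below the line at 10.50 and 6.95, and ATF3 above it at 4.96 and 7.58.

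The size of the response was compared over genes that changed at least 2-fold in the average of both lines. The median of the S401A response less the WT response, signed so that a smaller response in S401A is negative, was 0.03 over 2037 rising genes and -0.05 over 2174 falling genes, against a replicate SD of 0.023 and 0.033. Genes do not count as replicates, so these medians have no test. Simulated libraries without a line difference, as described for the odds ratios, gave medians of -0.0964 and -0.0221 for rising and -0.029 and -0.0247 for falling genes. The first was -0.07 without WT PMA replicate 2, -0.06 without WT PMA replicate 3, 0.06 without WT PMA replicate 1 and 0.07 without S401A PMA replicate 3. The second was -0.13 without WT PMA replicate 2 and -0.11 without replicate 3.

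The genotype calls in DMSO and in PMA overlapped, with 1117 genes higher in S401A in both, SIGLEC1, PRDM6 and CD209 among them, and 1149 lower in both, LYZ, TNF and C3 among them. Independent lists would share 251 and 237 genes. Opposite calls were made for 61 genes, IL1B among them, at 1.29 ± 0.13 in DMSO and -2.25 ± 0.10 in PMA. The contrasts share no library. The overlaps were 3182 and 3358 without WT PMA replicate 1, and without genes of chromosomes 10 and 12 they were 895 and 929.

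Genes called for genotype in PMA were also set against genes called for the average PMA effect. Both contrasts use all 6 PMA libraries, and WT PMA had a median SD of 0.438 log2 units against at most 0.11 in the other groups, so an odds ratio away from 1 can arise with no difference between the lines. Libraries without such a difference were therefore simulated in 2 ways, 10 times each, chosen after seeing the data, with genotype lists of the observed size taken by smallest p. In the first each group kept its own spread, and in the second WT PMA replicate 1 kept its deviation. The odds ratio of genes higher in S401A and lowered by PMA was 2.00, against a simulated median of 1.82 (1.61 to 1.92) in the first and 1.32 (1.16 to 1.36) in the second. That of genes lower in S401A and raised by PMA was 1.69, against 2.04 (1.84 to 2.13) and 1.12 (1.04 to 1.17). Genes lower in S401A and lowered by PMA gave 0.956, against 0.616 (0.589 to 0.663) and 0.407 (0.369 to 0.425), and 0.577, 0.657 and 0.697 without WT PMA replicate 1, 2 and 3. Genes higher in S401A and raised by PMA gave 1.15, against 0.592 (0.572 to 0.663) and 0.796 (0.772 to 0.847), and 0.854, 0.955 and 1.01 without those replicates. Part of any excess may come from the shared libraries, and no test is drawn from these ratios. The first simulation called 272 to 378 genes for genotype in PMA, against 4255 observed, and the second 0.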

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

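The results below are those where the PMA response differed between the lines by the interaction test, and the tests of WT PMA replicate 1, of chromosomes 10 and 12 for their own genes, and of interferon-stimulated genes without that library or those chromosomes were chosen after the results had been seen.

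The interaction was called for 295 genes above 0 and 165 below. In 60 drawn relabelings of genotype within each treatment, 2 gave as many calls, the real one included, with 460 for the real labels and 1028 for the highest other. Relabelings that mix the lines within a treatment put the genotype difference, called at 3459 genes in DMSO and 4255 in PMA, into the spread. Their low counts are thus no measure of chance, so whether chance can be excluded is not settled by them. The relabelings that exchanged the genotype of all 6 DMSO libraries and of 2 PMA libraries called 1028, 15 and 11 genes. Exchanging all 6 DMSO libraries makes the interaction add the genotype differences in DMSO and in PMA instead of subtracting them. The count of 1028 is thus no measure of chance either, and what sets it apart from 15 and 11 was not tested.

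Interaction log2 fold changes above 0 included DTX4 4.02, MPEG1 3.16, TDO2 3.00, CYP1B1 2.82, LPL 2.47, TIMP3 2.10, FNIP2 2.00 and GPNMB 1.54. A value above 0 need not mean a higher level with PMA in S401A. CYP1B1 was at 3.7 to 4.1 CPM in S401A DMSO and 52.7 to 61 in S401A PMA, against 40.9 to 48.2 and 42 to 115.5 in WT. Of early response and kinase pathway genes, they were ATF3 2.63, NR4A1 2.37, DUSP4 1.00 and MAPK13 1.14. Interferon-stimulated genes gave XAF1 2.47, IFIT5 2.10, MX2 2.04 and RIGI 1.49. Lysosomal and mTORC1 genes gave ASAH1 1.26, ATP6V1A 1.00, CTNS 0.81 and RRAGC 0.70, and NRF2 targets SRXN1 1.19 and GCLC 0.96. Values below 0 were IL1B -3.54, CNR1 -2.60, CXCL1 -2.29, ICAM1 -2.27, COL9A3 -2.17, TNFAIP8 -1.59, KLF4 -1.52, TRAF1 -1.30, TLR2 -1.04, DEPTOR -1.04, BTG2 -0.94, SPP1 -0.94 and NFKBIA -0.68. Of these 35 genes, 7 lost the call when single libraries were left out. CTNS did so without S401A PMA replicate 1 (0.77). DEPTOR did so without WT DMSO replicate 1 (-1.05), 2 (-1.05) or 3 (-1.01), S401A DMSO replicate 1 (-1.03) or 2 (-1.02) or S401A PMA replicate 1 (-1) or 2 (-1.02). DUSP4 did so without WT DMSO replicate 1 (0.83) or 2 (1.03), S401A DMSO replicate 1 (0.99) or 3 (0.94) or S401A PMA replicate 1 (0.99), 2 (1.02) or 3 (1.01). GCLC did so without WT DMSO replicate 1 (0.97), 2 (0.93) or 3 (0.98), S401A DMSO replicate 1 (0.94), 2 (0.95) or 3 (0.99) or S401A PMA replicate 1 (0.97), 2 (0.96) or 3 (0.95). NFKBIA did so without WT DMSO replicate 1 (-0.73), 2 (-0.65) or 3 (-0.65), S401A DMSO replicate 1 (-0.64), 2 (-0.70) or 3 (-0.69) or S401A PMA replicate 1 (-0.68), 2 (-0.64) or 3 (-0.72). RRAGC did so without WT DMSO replicate 2 (0.71) or 3 (0.64), S401A DMSO replicate 2 (0.70) or 3 (0.65) or S401A PMA replicate 1 (0.72), 2 (0.71) or 3 (0.68). SPP1 did so without WT DMSO replicate 1 (-0.96) or 3 (-0.86), S401A DMSO replicate 1 (-0.86) or 3 (-0.90) or S401A PMA replicate 1 (-0.87) or 2 (-0.92). Calls were also lost on log2(FPKM + 1) (BTG2 -0.67, KLF4 -1.10, TLR2 -0.81, GCLC 1.09) and on log2(FPKM + 0.1) (BTG2 -0.75, KLF4 -1.30, TLR2 -0.85, GCLC 1.15, SPP1 -0.83, TRAF1 -1.09, NFKBIA -0.50). With length-corrected offsets they were lost by SPP1 -0.81, NFKBIA -0.47, DUSP4 0.76, with the replicate block by SPP1 -0.94, RRAGC 0.70, DEPTOR -1.03, NFKBIA -0.68, GCLC 0.98, DUSP4 1.00, and without a filter by NFKBIA -0.68, GCLC 0.96. Among gene lists, camera gave an interaction adjusted p of 1.41e-20 for interferon-stimulated genes, 0.00626 for the nuclear respiratory chain and 0.00898 for NRF2 and metallothionein genes. The last 2 were not called with an estimated correlation (adjusted p = 0.694 and 0.416), and without WT PMA replicate 1 the respiratory chain was at 0.868 and NRF2 genes at 2.32e-09.

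WT PMA replicate 1 lay far from replicates 2 and 3, and its deviation fell by 0.451 log2 units per doubling of exon length. With each library's trend on length removed, its median absolute deviation was still 0.487, above the 0.279 of the next library, which argues against gene length as the whole cause. On 1591 genes that PMA changed at least 4-fold in S401A it lay at 0.944 of the way from WT DMSO to WT PMA replicates 2 and 3. On 429 genes that differed at least 4-fold by genotype in DMSO it lay at 0.102 of the way to S401A PMA. These places argue against a DMSO library, a mixture made up mostly of one, or an S401A library. A mixture with a small share of DMSO counts could lie near the first place and is not excluded. A difference in RNA quality or library preparation may account for the deviation and stays open, as do the culture and its state, since no label describes either.

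Genes of chromosome 10 were higher and those of chromosome 12 lower in every S401A library, by 0.45 to 0.537 and by -0.304 to -0.341 log2 units against WT libraries of the same treatment, where WT libraries stayed within 0.081 except WT PMA replicate 1 at -0.17 on chromosome 10. A gain of chromosome 10 in the S401A line, or a loss of it in the WT line, may account for its genes. All 10 of its segments lay beyond the shuffled limit in DMSO and in PMA. Each line was measured only against the other, so these values do not say which line changed. On chromosome 12, 14 of 15 segments had a median under 0 in DMSO and in PMA, but 10 lay beyond the limit in DMSO and 6 in PMA. The first 3 did in neither (medians from -0.139 to 0.103 and from -0.155 to 0.031). A loss of part of it in S401A, or a gain in WT, thus cannot be told apart from a lower expression of many of its genes in S401A. Segments beyond the limit held 15.1% of the 3447 placed genes called in DMSO, which argues against each gene's own copy number as the whole cause of the genotype difference. Own copy number as a part of the cause is not excluded by this share. No DNA data were used here, effects of these segments on genes elsewhere were not tested and stay open, and a change that came with the edited clone and an effect of the S401A codon on other genes are not separable in these groups.

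Interferon-stimulated genes were higher in S401A, more so with PMA, though in DMSO the list was not called with an estimated correlation (adjusted p = 0.057). Without WT PMA replicate 1 the list's interaction kept a camera adjusted p of 2.04e-20, which argues against that library as the whole cause. Over all its alternatives the list's interaction ran from 2.04e-20 to 0.00116, the latter with an estimated correlation and that library kept. Of the 30 members called higher in PMA, 13.3% lay in raised segments, and without genes of chromosomes 10 and 12 the list's camera adjusted p in PMA was 4.21e-13 (0.00102 with an estimated correlation), which argues against the members' own copy number, and against members on those chromosomes, as the whole cause. A part played by either is not excluded. With those chromosomes kept, the list's adjusted p in PMA ran from 5.54e-17 to 0.00191 over its alternatives. A hypothesis that the knock-in line has a raised interferon response, from the edit, from the clone or through genes on a gained or lost segment, stays open and was not tested further, as does any difference in culture between the lines.

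Each comparison of 2 groups has 10 splits of its 6 libraries, too few for a share under 0.05. With edgeR on those libraries alone, 1 of the 10 splits gave as many calls as the real one in each comparison, namely the real one. The real splits called 5082 genes for PMA in WT, 11202 for PMA in S401A, 9048 for genotype in DMSO and 1644 for genotype in PMA. Each of the other splits called 0 genes, with at most 467, 48, 399 and 1133 at an unadjusted p under 0.05. Those splits mix the 2 groups compared, which puts the difference between the groups into the spread. Their low counts are thus no measure of chance.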

How the results depend on the processing

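The length-corrected offsets, voom with library quality weights, lists without WT PMA replicate 1 and results without genes of chromosomes 10 and 12 were chosen after seeing the data. Counts are given as genes higher and lower, and the cause of a change was not tested unless named. RLE factors and both filters left each count of called genes within 1.5 times. The replicate block brought the respiratory chain list under 0.05 for PMA in WT (0.0493) and genotype in PMA (0.0392), and changed no other list's call. Of the values of named genes under all alternatives, 5576 kept their side of the threshold without a called change of sign. Another 168 lost the call, 44 gained it and 1 was called with the opposite sign, TNF in the interaction at -1.12 on log2(FPKM + 1). The 5576 include uncalled values that changed sign, such as TFEB for genotype in PMA, from -0.32 to 0.18 without WT PMA replicate 1. The simulated recovery is that of this depth and a spread pooled over all groups together, and depth was not varied.

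On log2(FPKM + 1) the counts were 1955 and 6561 for PMA in WT, 2362 and 5611 for PMA in S401A, 2919 and 1098 for genotype in PMA, 643 and 388 for the interaction, and on log2(FPKM + 0.1) 1972 and 6517 for PMA in WT, 2374 and 5397 for PMA in S401A, 2982 and 1149 for genotype in PMA. That table carries no composition factor, which shifts the median of all genes. The 2 groups alone gave 2413 and 2669 for PMA in WT, 5568 and 5634 for PMA in S401A, 4604 and 4444 for genotype in DMSO, 880 and 764 for genotype in PMA, with no spread shared from other groups. DESeq2 gave 555 and 381 for the interaction, a test in which 33.6% of its calls on interaction counts simulated with the same spread in all groups were false. Length-corrected offsets gave 2820 and 3185 for genotype in PMA, 498 and 346 for the interaction. Voom with quality weights, which gave WT PMA replicate 1 a weight of 0.017, gave 5812 and 5991 for PMA in WT, 6057 and 6190 for PMA in S401A, 4982 and 5294 for genotype in DMSO, 4956 and 4713 for genotype in PMA, 2310 and 1828 for the interaction.

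Same-numbered libraries had correlations of deviations from -0.441 to 0.297, with 5 of 18 over 0.1. With 3 libraries per group these values cannot tell whether replicate numbers pair the libraries, and the labels do not say. With the replicate block the interaction had 191 and 99 calls, and the median response of rising genes was 0.0664. That median was 0.216 and 0.227 on the FPKM scales and 0.0579 with length correction, and that of falling genes -0.127 and -0.199 on the FPKM scales.

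Leaving out each library in turn gave, from lowest to highest, 3120 to 5836 higher and 3283 to 5880 lower for PMA in S401A, 1120 to 4385 and 1153 to 4636 for genotype in DMSO, 1573 to 4679 and 1418 to 4448 for genotype in PMA, and 169 to 1600 and 80 to 1198 for the interaction. The highest of each was without WT PMA replicate 1, and 1120 was without WT DMSO replicate 2. Medians ran from -0.0682 to 0.0654 for rising and -0.125 to -0.0225 for falling genes. Overlaps of genotype calls ran from 809 to 3182 higher and 816 to 3358 lower, and were 3563 and 3697 with voom. Those lower in both numbered 634 and 689 on the FPKM scales and 1838 with length correction.

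The odds ratio of genes higher in S401A and raised by PMA ran from 0.854 to 1.29 over left-out libraries, reversing without WT PMA replicate 1 and at 0.955 without replicate 2. It was 1.09 with the stricter filter, and reversed at 0.982 with length correction and 0.789 with voom. That of genes lower in S401A and lowered by PMA ran from 0.577 to 1.12, reversed at 1.31 with DESeq2 and 1.36 without a filter, and was 0.832 on log2(FPKM + 1), 0.723 with length correction and 0.58 with voom.

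Of the 31 lists, camera called 11 higher and 1 lower for PMA in WT, 16 and 3 for PMA in S401A, 2 and 4 for genotype in DMSO, 4 and 4 for genotype in PMA and 2 and 1 for the interaction. With an estimated correlation these were 5 and 1 for PMA in WT, 6 and 1 for PMA in S401A, 0 and 0 for genotype in DMSO, 1 and 0 for genotype in PMA and 1 and 0 for the interaction. At an unadjusted p under 0.05 camera with an estimated correlation had 2 and 2 lists for genotype in DMSO, 2 and 4 for genotype in PMA and 1 and 1 for the interaction. At an adjusted p under 0.05 fry called 21 and 5 for PMA in WT, 21 and 6 for PMA in S401A, 7 and 10 for genotype in DMSO, 8 and 7 for genotype in PMA and 6 and 3 for the interaction. Fry asks whether a list moves one way, not whether it moves more than other genes. Without WT PMA replicate 1, camera called 10 and 3 for PMA in WT, 16 and 3 for PMA in S401A, 3 and 3 for genotype in DMSO, 4 and 2 for genotype in PMA and 6 and 1 for the interaction. Lists called only without that library, beyond those given with their comparison, were mitosis for PMA in WT (adjusted p = 0.0182) and the interaction (5.67e-05), autophagy for genotype in DMSO (0.0183), and mTORC1 (0.0478), cholesterol (0.000711) and ATF4 genes (0.00508) for the interaction.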

Other observations

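The counts of list members on log2(FPKM + 1) and with length-corrected offsets were chosen after seeing the data. Of LXR and PPAR lipid genes, 11 of 27 tested members rose and 10 fell with PMA in WT (11 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.56), against 9 higher and 12 lower on log2(FPKM + 1), and 10 rose and 11 fell in S401A (10 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.612), against 13 higher and 11 lower with length-corrected offsets. Among those that rose, PLIN2, which coats lipid droplets, went from 44.6 ± 1.4 to 1451 ± 292 CPM in WT (SD, n = 3), and PPARG, a nuclear receptor of lipid metabolism, from 13.4 ± 0.433 to 121.4 ± 4.75 CPM. Of cholesterol synthesis and SREBP2 target genes, 9 of 24 tested members rose and 2 fell in WT (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0606), against 6 higher and 8 lower on log2(FPKM + 1). In S401A 11 rose and 1 fell (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00772, adjusted p = 0.116 with an estimated correlation, 9 higher and 7 lower on log2(FPKM + 1)). INSIG1, a regulator of SREBP, rose by 1.63 ± 0.10 in WT and 1.96 ± 0.10 in S401A on the log2 scale. Of NRF2 and metallothionein genes, 10 of 20 tested members rose in WT (10 higher adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.248 with an estimated correlation, adjusted p = 0.0651 without WT PMA replicate 1, 7 higher and 3 lower on log2(FPKM + 1)) and 13 rose and 1 fell in S401A (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00041, adjusted p = 0.116 with an estimated correlation, 12 higher and 4 lower on log2(FPKM + 1)). HMOX1, the heme oxygenase gene, rose from 1.7 ± 0.148 to 97 ± 35 CPM in WT and from 1.32 ± 0.256 to 143 ± 6.86 CPM in S401A. Adhesion and matrix genes had 20 of 35 higher and 5 lower in WT (20 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.000204, adjusted p = 0.157 with an estimated correlation, 19 higher and 9 lower on log2(FPKM + 1)). MMP14, a membrane metalloproteinase, rose from 139 ± 4.6 to 1401 ± 72.6 CPM, and PLAUR, the urokinase receptor, from 20.8 ± 1.11 to 826 ± 243 CPM. Ribosome biogenesis genes and MYC targets had 19 of 36 higher and 1 lower in WT with PMA (19 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.248 with an estimated correlation, 7 higher and 4 lower on log2(FPKM + 1)), although MYC itself was lower.

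Markers of other cell types were mostly under the filter. Of T and NK cell markers 7 of 19 were tested, and with PMA in S401A 4 rose and 1 fell (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.116 with an estimated correlation). Of epithelial, fibroblast and endothelial markers 9 of 19 were tested, and 4 were lower in S401A with PMA (4 lower adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.14 with an estimated correlation, adjusted p = 0.0576 without WT PMA replicate 1 and 0.109 without genes of chromosomes 10 and 12). Of B and plasma cell markers 7 of 15 were tested and of erythroid and megakaryocyte markers 4 of 20, with camera adjusted p of 0.625 and 0.444 for PMA in WT. Myeloid progenitor and granule genes had 10 of 22 lower and 1 higher with PMA in WT (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.0569, adjusted p = 0.00161 without WT PMA replicate 1). There IRF8 went from 637 ± 12.8 to 189.6 ± 27.2 CPM and GFI1 from 267 ± 6.75 to 83.2 ± 14.9 CPM.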
